A study of Rattus norvegicus with 12 samples.

How the data were processed

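Total RNA from rat brain was extracted with Trizol, primed with a T16N2 DNA primer, reverse transcribed and labelled with Cy3, per the labels' protocols. Such a primer starts from runs of A, so the labelled RNA need not be circular. Each of the 12 samples was hybridised to its own one-colour Agilent array. The labels name 3 groups of 4 samples with replicate numbers 1 to 4 and call most of the samples biological replicates without tying them to animals, so p-values measure the spread between these samples. The labels conflict in places: the tissue field reads brain while descriptions name hippocampus, and the series design text applies the ischaemia to all groups while the control samples are labelled normal. Groups were taken from the sample titles.

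Images were read with Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes and per the file headers. The scanner files give processed spot intensity on a linear scale, from which Feature Extraction had already subtracted background and spatial trends, per the file headers, and mean spot and median local background intensity with no correction. Other columns are 0 or 1 flags per spot, set by Feature Extraction per the file headers, for signal well above background, outliers and saturation. The deposited value table holds log2 values that the authors made from the same arrays. Set against the scanner values of the same array they correlated at r = 0.9995 or higher, every column had a median of 6.134, and they ran in the same direction. They are therefore log2 values that were not centred per gene. They were read as quantile normalized from the values, since no source used here names that step, and their counts of calls were near those with quantile normalization here (51 and 51, 1198 and 1201, 4706 and 4718). That table was used as an alternative. A genome build is named in the header but every probe's coordinate field reads unmapped, so no positions are given.

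Each array held 62976 spots, of which 61537 were not control spots and covered 60148 distinct probes. Spots flagged as outliers were left out and no spot was saturated. Processed signals were taken to log2, spots of a probe were averaged, and each array's 75th percentile was subtracted. Probes entered the test if well above background on every array of at least 1 group, which left 44719. The fit used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes) with 1 mean per group over all 12 arrays, so that the groups share an estimate of the spread, and Benjamini-Hochberg adjustment over the tested probes. A probe was called at an adjusted p under 0.05. A probe not well above background on any array of a group has only a bound there. Its fold is given as at least the mean of the brighter group over the mean, in the dimmer group, of the higher of the probe's own signal and the lowest signal well above background on that array. This limit differs between probes. On model replicate 3, RNO_CIRCpedia_5686_16_14 at a log2 level of -5.703 was not well above background, but RNO_CIRCpedia_2356_16_14 at -5.858 was. The bound is therefore approximate, and the true fold may be smaller.

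The rule for named features, fixed before the data were examined, took the largest rises and falls among called probes and left out unnamed ones. No file pairs probes with genes, so it was applied to probe IDs and limited to 2 rises and 2 falls per comparison. The fixed lists of cell type markers, inflammatory, synaptic, vascular and other genes could not be run for the same reason. CIRCpedia probes were tested as a set with camera at a preset correlation of 0.01, with an estimated correlation and with fry. The number of opposite calls and the correlation between comparisons were each set beside 100 simulations of unchanged groups that share the model arrays. For the opposite calls, scatter was drawn independently for each probe. For the correlation, the deviations of whole arrays from their group means were resampled.

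The fit was tested on simulated data in which 200 of 44710 probes were changed. Between model and control it recovered 52.2% of 1.5-fold, 77.6% of 2-fold and 95.5% of 4-fold changes, with 11 calls among unchanged probes. Between BHD and model it recovered 58.2%, 80.6% and 95.5%, with 6 such calls. Scatter was drawn as normal and independent for each probe, which leaves out scatter that probes of an array share. These shares and counts of calls hold for that setting and need not hold for the real arrays.

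Slide and scan were read from the headers. Control arrays filled row 1 and model arrays row 2 of slide 1, and BHD arrays filled row 1 of slide 2. The alternatives fixed at that same stage were quantile normalization, a percentile over probes well above background on all arrays, normexp background correction (offset 50) with either scaling, the deposited table, other filters on dim probes, fits on only the groups compared, a replicate block, other variance models, other thresholds, and leaving out each array in turn. A correction for GC content and centring on E1A spike-in probes were chosen after seeing the data. Figures were drawn with matplotlib.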

Results

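RNA from rat brain was measured on 12 one-colour microarrays in 3 groups of 4 samples. The control group was normal brain. The model group came from rats sampled at day 7 after embolization of the middle cerebral artery, which blocks the main arterial supply of one cerebral hemisphere. The BHD group came from model rats given Buyang Huanwu Decoction, a multi-herb preparation of Chinese medicine, also sampled at day 7. The series addresses circular RNAs, which are closed RNA loops joined by back-splicing, and their network with microRNAs and messenger RNAs. The array held 60148 distinct 60-base probes, of which 3046 carry a name that refers to CIRCpedia, a collection of circular RNAs, and 57102 carry the prefix rclstr. The files do not pair any probe with a gene and do not say which kind of RNA the rclstr probes report, so probes are given by ID and sequence, at most 2 that rose and 2 that fell per comparison. Each level below is a log2 signal relative to the 75th percentile of the same array, and each change is a difference of such levels.

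Signal was even across the arrays. The share of probes well above background ran from 73.2% (BHD replicate 3) to 77.3% (model replicate 3), and the 75th percentile of the signal ran from 396.8 to 451.9 units. CIRCpedia probes were detected more often than rclstr probes: 95.7% of them against 73.2% were well above background on every array of at least 1 group and were tested, which gave 2915 CIRCpedia and 41804 rclstr probes, 44719 in all. Arrays correlated at r of 0.979 to 0.9932 across tested probes, which are not independent replicates, and no pair of arrays held the same values. On the first principal component (28.1% of the variance) the control arrays lay between -55.0 and -30.8, the model arrays between -12.4 and 25.5, and BHD replicates 1, 3 and 4 between 43.4 and 46.2. BHD replicate 2 lay at -1.5 and stood apart at 66.8 on the second component (16.5%). The 4 control and the 4 model arrays shared slide 1. Control arrays lay on row 1 and model arrays on row 2, so group and row cannot be told apart between them. The 4 BHD arrays lay on row 1 of slide 2, which was scanned separately.

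**Figure D1:**
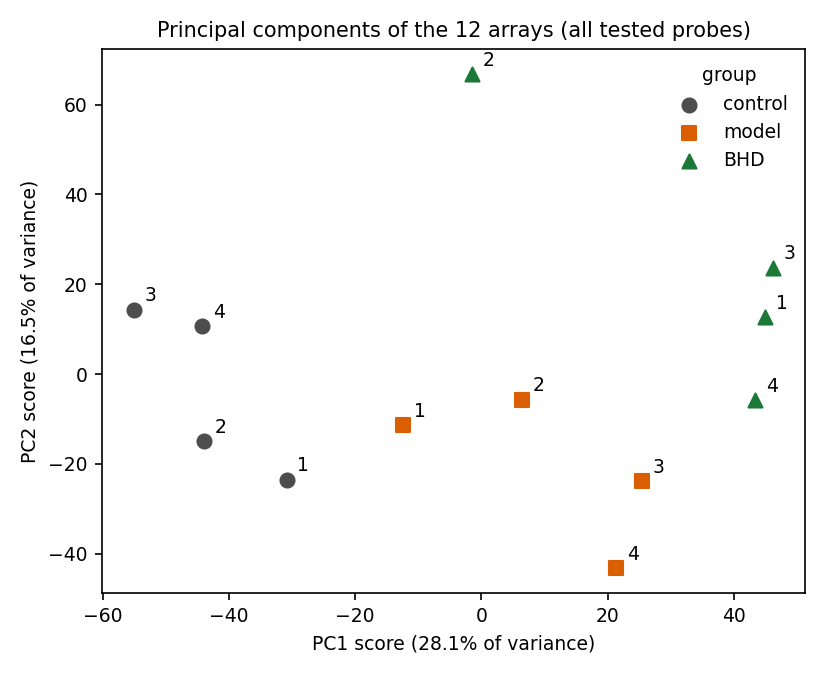
Principal component scores of the 12 arrays over all tested probes, PC1 (28.1% of variance) against PC2 (16.5%); each point is an array, its shape and colour give the group and its number the replicate. Control, model and BHD arrays follow each other along PC1, except BHD replicate 2, which lies at -1.5 on PC1 and 66.8 on PC2.

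The first comparison asked which RNAs differ between the ischaemia model at day 7 and normal brain. At adjusted p under 0.05 (limma), 21 of 44719 probes differed, 10 higher and 11 lower in the model, and 10 of them had a fitted change of 2-fold or more. Such counts include probes near background in a group, whose changes have only an approximate bound. Named probes are those with the largest fitted log2 changes among called probes. The first rise was at rclstr_33535_378_4 (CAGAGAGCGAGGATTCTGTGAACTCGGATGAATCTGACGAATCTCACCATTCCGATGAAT), 59.2-fold higher in the model (log2 change 5.89 ± 0.81 SE, adjusted p = 0.0387). Its level was -3.93 ± 0.80 (SD, n = 4) in control, 1.95 ± 1.55 in model and 1.17 ± 1.37 in BHD brain, and all 12 arrays measured it well above background. With normexp background correction before percentile scaling (normexp below) its log2 change was 4.31, and without model replicate 4 it was 5.13. Its call in this comparison was lost in 10 other settings (adjusted p 0.0535 to 0.117), among them the fit of only model and control (0.0535) and the fit with no filter on dim probes (0.0627). The next rise was at rclstr_53789_185_16 (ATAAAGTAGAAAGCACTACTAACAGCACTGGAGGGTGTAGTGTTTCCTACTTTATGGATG), which was not well above background on any control array and was at least 1.85-fold higher in the model (adjusted p = 0.00724). With normexp, which adds 50 units to each signal and so shrinks changes of dim probes, its log2 change was 0.21 and its call was lost (adjusted p = 0.0929). The first fall was at rclstr_27469_574_10 (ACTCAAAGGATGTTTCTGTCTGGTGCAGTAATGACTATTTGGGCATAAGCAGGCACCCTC), from -2.20 ± 0.29 to -5.95 ± 0.74 (log2 change -3.75 ± 0.34 SE, adjusted p = 0.00724). It was well above background on 4 control arrays, 1 model array and 1 BHD array, so the size of this fall is not well measured, and normexp gave -1.27. The probe rclstr_21070_1653_3 (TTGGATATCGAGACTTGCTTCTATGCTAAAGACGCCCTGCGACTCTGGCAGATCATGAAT) fell from -1.94 ± 0.57 to -4.33 ± 0.16 (log2 change -2.40 ± 0.31 SE, adjusted p = 0.0367), and its call was lost in 9 other settings (adjusted p 0.0518 to 0.117). With normexp its log2 change was -1.09.

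All 21 called probes were rclstr probes. None of the 2915 CIRCpedia probes was called by limma, and 420 of them had an unadjusted p under 0.05, where 146 would be met by chance. Over all tested probes, 7868 had an unadjusted p under 0.05 against 2236 by chance. As a set, CIRCpedia probes had a median log2 change of -0.03 against 0.01 for rclstr probes (camera, adjusted p = 0.0567, and 0.562 with an estimated correlation). The E1A spike-in probes, which report an added viral RNA, moved with this comparison. The mean of 8 E1A probes was lower by a log2 difference of -0.17 in model than in control arrays, on the same slide (exact permutation test, two-sided, p = 0.0286, adjusted p = 0.0429 over 3 comparisons). The 3′ to 5′ difference of the Rat-GAPDH control probes, a measure of RNA or labelling quality, was 2.90 ± 0.06 in model and 3.04 ± 0.04 in control arrays (exact permutation test, p = 0.0286, the smallest 4 against 4 can give, adjusted p = 0.0858 over 6 tests). That of the Rat-PGK1 probes differed by -0.11 (exact permutation test, p = 0.229, adjusted p = 0.429). With each array centred on the E1A probes in place of its 75th percentile, the median change of all tested probes was 0.18 and 2243 probes were called, 2139 higher and 104 lower. The count was 51 under quantile normalization and 230 under quantile normalization after normexp background correction. It also depended on single arrays: it was 9, 9, 6 and 10 without control replicates 1, 2, 3 and 4, 107, 3 and 6 without model replicates 1, 2 and 3, and 11, 57 and 5 without BHD replicates 1, 2 and 3, whose arrays enter the shared estimate of the spread.

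The second comparison asked which RNAs differ between treated and untreated model animals. Between BHD and model, 1428 probes differed, 309 higher and 1119 lower with BHD. Of these, 264 had a fitted change of 2-fold or more, 35 up and 229 down, and the median size of a called change was 0.68 log2 units. Ranked by fitted log2 change, which is not well measured where a group is near background, the first rise was at rclstr_42850_435_13 (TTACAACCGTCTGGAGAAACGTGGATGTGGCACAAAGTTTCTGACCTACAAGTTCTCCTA), at least 2.23-fold higher with BHD (adjusted p = 0.00265, limma). It was well above background on 4 control arrays, on 0 model arrays and on 4 BHD arrays. With normexp its log2 change was 0.34. The probe rclstr_47224_396_13 (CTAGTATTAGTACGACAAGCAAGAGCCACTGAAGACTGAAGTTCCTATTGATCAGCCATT) was well above background on the 4 BHD arrays alone and was at least 1.79-fold higher there (adjusted p = 0.0149), with a log2 change of 0.29 with normexp. The first falls in that ranking were at rclstr_14533_1559_5 (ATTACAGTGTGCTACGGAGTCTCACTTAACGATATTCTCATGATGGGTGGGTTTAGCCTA), at least 2.51-fold lower (adjusted p = 0.00978), and rclstr_6234_1382_19 (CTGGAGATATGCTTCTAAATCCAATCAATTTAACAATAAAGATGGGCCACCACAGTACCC), at least 1.45-fold lower (adjusted p = 0.00138). Both of these were not well above background on any BHD array, and their log2 changes were -0.33 and -0.21 with normexp, where the first lost its call (adjusted p = 0.055, and 0.0452 with normexp before quantile normalization).

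The calls of each class divided differently between higher and lower, a difference that was not tested. Of 97 called CIRCpedia probes, 75 were higher and 22 lower with BHD (77.3% higher), whereas 17.6% of the called rclstr probes were higher, or 19.7% when these were weighted to the levels of the CIRCpedia probes. Under quantile normalization 103 CIRCpedia probes were higher and 17 lower. The CIRCpedia probes as a set had a median log2 change of 0.02 against -0.03 for rclstr probes (camera, adjusted p = 0.00101), a call that was lost with an estimated correlation between probes (adjusted p = 0.426) and with fry (adjusted p = 0.348). Falls were most frequent among dim probes: with the tested probes parted by level into 4 groups of equal size, 86.0% of the 637 calls in the dimmest group were lower with BHD, against 52.3% of the 109 calls in the brightest.

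Control probes for sequences not labelled as rat also moved between BHD and model. Of 36 such probes well above background on all arrays, 7 were called (19.4%), against 3.19% of the tested probes. None was called by limma between model and control, where 0.05% of tested probes were called. At unadjusted p under 0.05 (limma), 21 of the 36 passed there (58.3%, against 17.6% of tested probes). Between BHD and model 30.6% passed, against 17.1% of tested probes, so control probes moved within slide 1 too. Between BHD and control, which also crosses the slides, 13.9% were called against 10.74% of tested probes. E1A and DCP probes make up most of these 36, and most of them moved alike between model and control, so they are not independent and no p-value is given for these rates. The control probes ERCC-00012_90, ERCC-00028_121, ERCC-00062_278 and ETG05_66023 were called lower in both comparisons across slides (-0.42, -0.84, -0.46 and -0.48 for BHD minus control). They differed by -0.08 to 0.05 between model and control. These 4 were dim, with mean log2 signals of 4.3 to 5.1, and the rates above were not matched for level. Among tested probes in the dimmest of the 4 groups by level, 637 of 11180 were called between BHD and model, 548 of them lower. The control probe ERCC-00028_121 was lower with BHD by a log2 change of -0.76 ± 0.07 SE (limma, adjusted p = 0.00132) and the control probe DCP_22_7 was higher by 0.42 ± 0.08 (adjusted p = 0.0157). The 4 Rat-GAPDH and Rat-PGK1 control probes differed by -0.15 to 0.00, with no call. BHD and model arrays lie on different slides and on different rows, so treatment cannot be told apart from slide or row in this comparison. The share of lower calls was 78.4%, and 68.3% under quantile normalization (381 higher, 820 lower), 66.7% with normexp before it (518 higher, 1039 lower) and 90.2% with E1A centring (194 higher, 1789 lower). The count was 712, 864, 934 and 856 without model replicates 1, 2, 3 and 4, and 705 and 755 without BHD replicates 1 and 3.

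**Figure D2:**
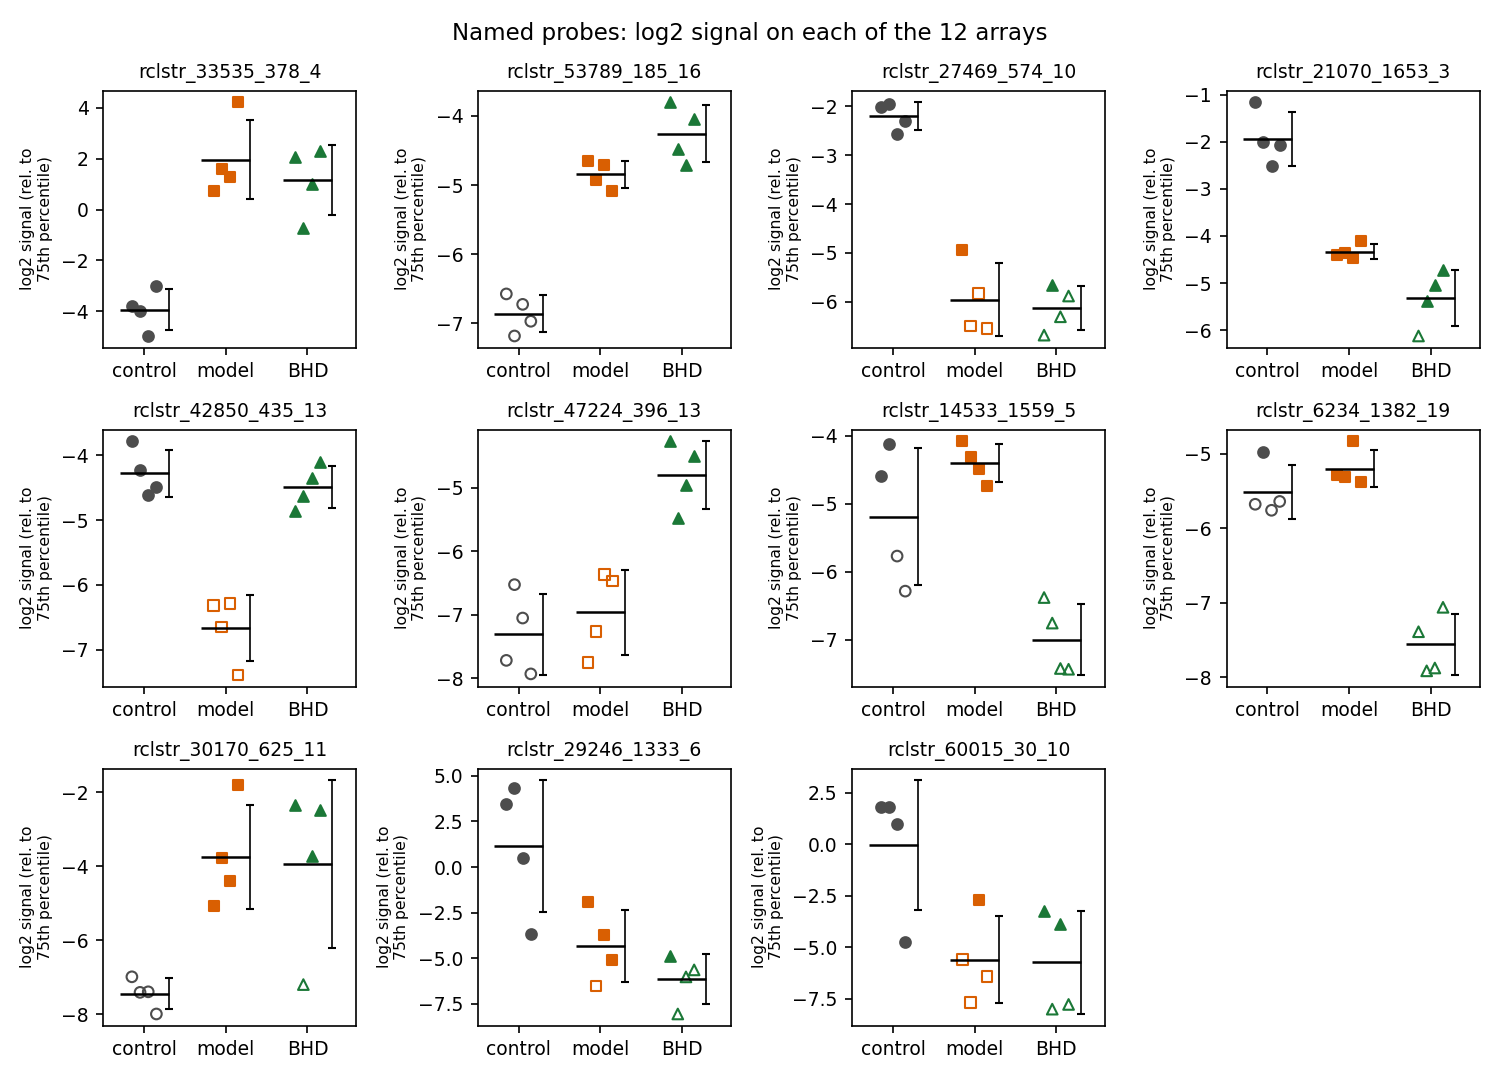
Log2 signal relative to the array's 75th percentile for the 11 named probes on each of the 12 arrays; filled symbols are arrays where the probe was well above background, open symbols where it was not, horizontal lines are group means and bars are ± SD (n = 4). rclstr_33535_378_4 lies at -3.93 on average in control and at 1.95 and 1.17 in model and BHD arrays, and rclstr_42850_435_13 is not well above background on any of the 4 model arrays.

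**Figure D3:**
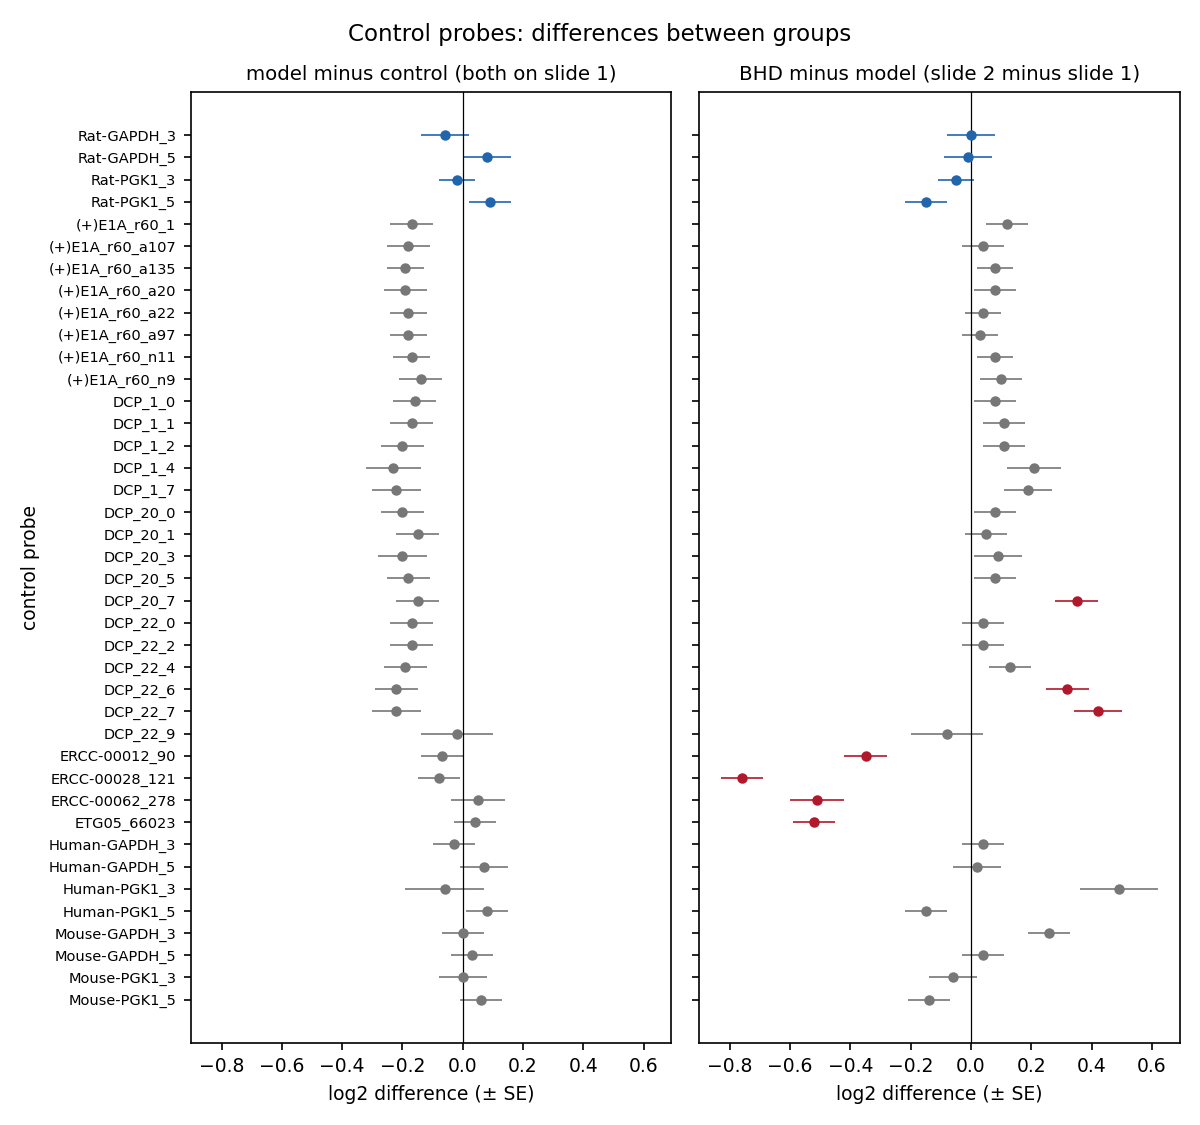
Log2 differences (± SE, 4 arrays per group) of control probes well above background on all arrays, for model minus control on slide 1 (left) and BHD minus model across slides (right); blue marks the 4 rat probes, grey other control probes and red those past an adjusted p of 0.05. Other control probes range from -0.23 to 0.08 on the left and from -0.76 to 0.49 on the right.

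Whether changes of the model were turned back in treated animals was examined with both comparisons together. Only the model arrays lay on row 2 of a slide, while control and BHD arrays lay on row 1. A difference between rows would by itself give opposite signs in these comparisons, so reversal cannot be told apart from position on the slide. In all, 5 probes were called in both with opposite signs, 3 that fell in the model and rose with BHD and 2 that rose and then fell. The clearest was rclstr_42850_435_13, with log2 changes of -2.38 in the model and 2.18 with BHD, and a difference from control of -0.21 (adjusted p = 0.651). Chosen after their values were seen, rclstr_905_1049_5 changed by -1.58 and then 1.05, rclstr_49208_641_34 by 1.74 and then -1.05, and rclstr_64122_126_20 by 0.67 and then -0.44. Their differences from control were -0.53, 0.69 and 0.23 in that order, none called (limma, adjusted p = 0.139, 0.0926 and 0.133). A further rclstr probe changed by -0.95 and then 0.51, and was still called lower than control (-0.43, limma, adjusted p = 0.0452). The 3 probes that fell in the model were not well above background on any model array, so the sizes of their changes are not well measured. Independent lists would share 0.076 and 0.25 probes in these directions, a value that leaves out the shared model arrays, which favour opposite signs. Unchanged groups sharing the model arrays, simulated with independent scatter for each probe, gave 0 opposite calls in 100 simulations. This value leaves out real changes, without which few calls are made at all. It also leaves out scatter that probes of an array share, so it cannot decide whether the 5 arose by chance. No call was made in the same direction in both comparisons.

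Across 44710 probes, which are not independent replicates, the log2 changes of the comparisons correlated at r = -0.22. Both comparisons use the same model arrays. Unchanged groups sharing them, simulated by resampling the deviations of whole arrays, gave r = -0.47 on average (95% of simulations from -0.82 to 0.27). The covariance was -0.0213 against -0.0193 in the simulation, a difference of -0.002. With the model arrays split 2 and 2 between the comparisons, r was -0.02 on average over the 6 splits (-0.12 to 0.11), and no split gave an opposite call, since limma called no probe between BHD and model with 2 model arrays. The count of opposite calls was 23 under normexp and quantile normalization and 164 with E1A centring. It was 3 and 1 without control replicates 2 and 3, 0, 2 and 2 without model replicates 2, 3 and 4, and 2, 9, 1 and 3 without BHD replicates 1, 2, 3 and 4.

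The third comparison asked which RNAs differed from normal brain in treated animals. Between BHD and control, 4802 probes differed, 1722 higher and 3080 lower with BHD, and 623 of them had a fitted change of 2-fold or more, 248 up and 375 down. The first rise by fitted log2 change was again at rclstr_33535_378_4, 34.3-fold higher with BHD (log2 change 5.10 ± 0.81 SE, adjusted p = 0.00478, limma), with a log2 change of 3.53 with normexp and of 5.73 without BHD replicate 2. The probe rclstr_30170_625_11 (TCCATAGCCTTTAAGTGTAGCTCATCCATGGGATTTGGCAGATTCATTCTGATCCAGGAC) was not well above background on any control array and was on 4 model and 3 BHD arrays. It was at least 3.48-fold higher with BHD (adjusted p = 0.0433), a call lost in 15 other settings (adjusted p 0.0504 to 0.118), among them normexp, with a log2 change of 0.77. The fitted log2 change was 3.51, and 4.59 without BHD replicate 2. The first falls were at rclstr_29246_1333_6 (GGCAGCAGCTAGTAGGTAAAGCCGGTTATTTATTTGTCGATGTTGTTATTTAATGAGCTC), from 1.15 ± 3.61 to -6.15 ± 1.36 (log2 change -7.30 ± 1.58 SE, adjusted p = 0.0169), and rclstr_60015_30_10 (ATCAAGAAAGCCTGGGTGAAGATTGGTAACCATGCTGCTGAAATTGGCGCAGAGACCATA), from -0.05 ± 3.17 to -5.74 ± 2.51 (log2 change -5.69 ± 1.66 SE, adjusted p = 0.0497). They were well above background on 4 control arrays each and on 1 and 2 BHD arrays, so the sizes of these changes are not well measured, and normexp gave -4.28 and -3.13. Single arrays moved both changes. For rclstr_29246_1333_6 it was -6.53, -6.24 and -8.91 without control replicates 1, 2 and 4 and -6.66 without BHD replicate 2. For rclstr_60015_30_10 it was -5.08, -5.08 and -7.26 without control replicates 1, 2 and 4, and -6.52, -4.93, -6.31 and -5.01 without BHD replicates 1, 2, 3 and 4. The call at rclstr_60015_30_10 was lost in 19 other settings (adjusted p 0.0504 to 0.117), among them quantile normalization (0.0575) and the deposited values (0.0576). Control arrays differed widely at both: rclstr_60015_30_10 was at -4.76 in control replicate 4 and between 0.98 and 1.80 in the other 3.

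Of 269 called CIRCpedia probes, 143 were higher and 126 lower with BHD (53.2% higher), against 34.8% of the called rclstr probes. Under quantile normalization 201 CIRCpedia probes were higher and 112 lower. As a set they did not differ from rclstr probes (camera, adjusted p = 0.182, and 0.564 with an estimated correlation). The 3′ to 5′ difference of the Rat-GAPDH probes was 2.91 ± 0.07 in BHD and 3.04 ± 0.04 in control arrays (exact permutation test, p = 0.0286, adjusted p = 0.0858), and that of the Rat-PGK1 probes differed by -0.01 (exact permutation test, p = 0.914, adjusted p = 0.914). The E1A probes were lower with BHD by a log2 difference of -0.10 (exact permutation test, p = 0.0286, adjusted p = 0.0429). Slide and treatment cannot be told apart here either. The share of lower calls was 64.1%, and 53.6% under quantile normalization (2191 higher, 2527 lower), 52.7% with normexp before it (2624 higher, 2923 lower) and 35.4% with E1A centring, which turned the balance (2678 higher, 1468 lower). The count was 7981 with array weights, 2727, 2400 and 2633 without control replicates 2, 3 and 4, and 2564 and 2506 without BHD replicates 1 and 3.

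A single F test over the 3 groups called 3388 probes (limma, adjusted p under 0.05), 194 of them CIRCpedia probes. It was 2052, 1859 and 2058 without control replicates 2, 3 and 4, and 1630 and 1621 without BHD replicates 1 and 3. With 4 arrays per group, the 95% interval of a probe's change had a median width of ± 0.27 log2 units, and the number of arrays limits the precision of each value.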

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

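The GC correction and the tests of the slide and of other tissue in this part were chosen only after the results were seen.

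A chance split of the arrays is argued against for each count of probes that differed between a pair of groups. Of the 35 splits of 8 arrays into 4 and 4, only the real one, 1 split, gave as many calls: 21 against at most 6 between model and control, 1428 against at most 16 between BHD and model, and 4802 against at most 20 between BHD and control. This 1 of 35 is the smallest share the test can give, and it was not adjusted over the comparisons. Of 100 regroupings of the 12 arrays, 1 (the real one) gave as many F test calls, 3388 against at most 1696. For probes with opposite changes, 3 of 100 regroupings, the real one included, gave 5 or more, and the highest of the others gave 861. Regrouping all 12 arrays tests for no difference among the groups at all, not for reversal. It therefore cannot decide whether the opposite calls arose by chance, and this count of 5 carries little weight. For the correlation of the changes, 94 of 100 regroupings gave a value as negative as -0.22, so chance cannot be excluded there.

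The probes that differed between BHD and model are confounded with the slide and with the row on it. A trend with GC content as the whole cause is argued against in so far as 83.1% of the called probes were still called after GC correction. Probe GC content lay mostly between 40% and 46.7%, and its rank correlation with the changes was -0.07, so the correction had little to remove. A difference in hybridisation between the slides remains open and may account for part of the calls: 19.4% of the control probes not labelled rat were called, 3 higher and 4 lower, against 3.19% of tested probes. The 4 lower ones were also called lower in BHD versus control (-0.84 to -0.42) and differed by -0.08 to 0.05 within slide 1, though the rate in BHD versus control was 13.9% against 10.74% of tested probes, and the 3 higher ones are DCP probes, which are not independent. The 4 lower ones were dim (mean log2 signals 4.3 to 5.1), where falls were frequent among tested probes too. The rates were not matched for level. Within slide 1, 58.3% of the control probes not labelled rat had an unadjusted p under 0.05 (limma) between model and control, against 17.6% of tested probes. Shifts of control probes were thus not limited to a change of slide. An effect of the decoction stays open as well, untested, because no array of another group in this series lay on slide 2.

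The 21 probes that differed between model and control come from a comparison within slide 1. Each group filled its own row there, so a difference between rows cannot be told apart from one between groups. Sequence shared between probes does not account for the number of calls, since 0 of the 21 share 20 or more bases with another called probe. Unequal amounts of another tissue in the samples would make residuals within groups rise and fall together, and the median absolute correlation among the called probes was 0.26, against 0.29 for random probes (0.21 to 0.46). This leaves it open, since called probes were selected for small spread within groups and 2 of them, rclstr_33535_378_4 and rclstr_27469_574_10, belong to sets b and d described below, whose members co-vary within groups (median r 0.76 and 0.59). The difference between ischaemic and normal brain named by the design also stays open as untested.

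Among 69 groups of 4 values examined, 10 held an array far from the others, where chance gives about 3.5. BHD replicate 2 had a first component score of -1.5, while the nearest BHD array was at 43.4. BHD replicate 1 had a 75th percentile signal of 435.6 units against 410.9 for the nearest, and a 3′ to 5′ difference of the Rat-PGK1 probes of 6.59 against 6.38. Control replicate 4 had 76.03% of probes well above background against 76.87% for the nearest. At rclstr_60015_30_10 control replicate 4 had a level of -4.76 against 0.98 for the nearest. At rclstr_6234_1382_19 control replicate 2 had -4.97 against -5.64, and model replicate 3 had -4.83 against -5.29. Of the 4 sets of co-varying probes described under the other observations, set a was at -3.58 in model replicate 2 against -3.02 for the nearest, set b at -1 in model replicate 4 against -2.77, and set c at -2.75 in control replicate 1 against -3.88. The control probe Mouse-GAPDH_3, which no comparison of rat probes uses, was higher on each BHD array than on every control array, with a mean log2 difference of 0.26.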

How the results depend on the processing

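GC correction, E1A centring and the alternatives for the CIRCpedia set were chosen only after the data were seen. Between BHD and model that set lost its call with an estimated correlation (adjusted p = 0.426) and with fry (0.348) and kept it with quantile normalization (0.00306). The 12 named results, and 8 for CIRCpedia probes ranked alike, kept their direction under every setting run, while 400 values kept the call and 86 lost it. The correlation stayed negative, between -0.30 and -0.19 over the other settings and from -0.32 to -0.10 over arrays left out. Causes were not tested unless stated.

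The model versus control count was 51 with quantile normalization and with the deposited values, 53 and 230 with normexp before percentile scaling and before quantile normalization, 10 without a filter on dim probes and 35 with probes above background on all arrays. It was 56 with trend and robust eBayes, 116 with array weights, 45 with GC correction, 2243 with E1A centring, which shifts all probes by 0.18, and 281 at adjusted p under 0.1. At unadjusted p under 0.05 and 2-fold it was 554. Arrays left out gave 3 to 107. Of the 21 probes, 20 were also called with quantile normalization, 12 and 18 with normexp (percentile, quantile) and 7 without the filter.

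The BHD versus model count was 940 without the filter, 870 in a fit of those groups only (fewer arrays), 2646 at adjusted p under 0.1 and 491 at unadjusted p under 0.05 and 2-fold, and 705 to 1487 over arrays left out. The BHD versus control count was 7981 with array weights, 8222 and 976 at those thresholds, and 2400 to 5877 over arrays left out.

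Opposite calls numbered 2 with the percentile over probes above background on all 12 arrays, 8 and 23 with normexp (percentile, quantile), 3 without the filter, 12 with array weights, 164 with E1A centring, 35 at adjusted p under 0.1, 44 at unadjusted p under 0.05 and 2-fold, and 0 to 9 over arrays left out. The F test count was 2204 without the filter, 5697 with array weights, 5559 with E1A centring, 7019 at adjusted p under 0.1 and 1621 to 3979 over arrays left out.

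Residuals of model and BHD samples with the same number correlated at -0.11, 0.24, 0.19 and 0.21 (numbers 1 to 4), and the other 8 such pairs at -0.19 to 0.12. As 4 of 12 pairs were over 0.1 and 4 of 12 samples correlated best with their own number, the numbers were not taken to pair the samples. The replicate number of each array was also its column on the slide. Pairing by number and position by column therefore cannot be told apart, and a block by number is also a block by column. With the replicate number as a block, the counts were 12 (model versus control), 1020 (BHD versus model), 3472 (BHD versus control), 4 (opposite) and 2138 (F test), and r was -0.22. Under the block the calls at rclstr_21070_1653_3 (model versus control, adjusted p = 0.0835), rclstr_30170_625_11 (BHD versus control, 0.0605) and RNO_CIRCpedia_8135_8_24 (BHD versus model, 0.0595) ended. Slide and scan as blocks were not run, since each BHD array lies on slide 2 and slide 1 holds the other groups; the fit of only model and control, within slide 1, gave 17 calls, 8 of them among the 21. Gene list alternatives were not run for lack of gene names. Probes not well above background on a group's arrays, 4, 69 and 113 of the called probes in the order above, have only a bound there.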

Other observations

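The 200 most variable probes held 4 sets of 10 or more members that rose and fell together over the arrays (average linkage on correlations, height 0.3), none with a CIRCpedia member. These sets and their tests, the comparison of probes sharing sequence, and the choice of on or off probes with the test of slides and groups were chosen only after the data were seen. Set b (40 probes) was higher in all 4 model arrays than in every control array, at -2.41 ± 0.95 (SD, n = 4) against -4.88 ± 0.27, and BHD arrays were at -2.47 ± 1.2. Set d (11 probes) was lower in all model and BHD arrays, at -2.21 ± 1.1 and -2.03 ± 0.58 against 0.96 ± 0.29 in control. Each of these 4 differences from control had an exact permutation p of 0.0286, the smallest that 4 against 4 can give, and an adjusted p of 0.0858 over 12 tests, so none passed. The sets were formed from variation over these same 12 arrays, group differences included. The p-values of the sets therefore give no independent support for a group difference. Between BHD and model, set b differed by -0.07 (exact permutation p = 0.943) and set d by 0.18 (exact permutation p = 0.8). In BHD versus control limma called 23 of the 40 members of set b as higher and 10 of the 11 of set d as lower, but in model versus control, with set differences of 2.47 and -3.17, it called 1 member of each. Named probes among the members are rclstr_29246_1333_6 and rclstr_60015_30_10 in set a, rclstr_33535_378_4 and rclstr_30170_625_11 in set b, and rclstr_27469_574_10 in set d.

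The other sets overlapped between groups, and in BHD versus control limma called 20 of the 41 members of set a as lower and 11 of the 25 of set c as higher (set differences -2.76 and 2.27, exact permutation p = 0.114 and 0.0571, adjusted p = 0.171 and 0.114). Set a (41 probes) was at 0.85, 1.75, -1.34 and -3.32 in control replicates 1, 2, 3 and 4, and between -3.97 and -2.74 in all model and BHD arrays. Set c (25 probes) was at -2.75, -4.09, -3.95 and -3.88 in control replicates 1, 2, 3 and 4, at -3.55, -2.74, -0.87 and -1.82 in model replicates and at -0.59, -3.13, -0.74 and -1.13 in BHD replicates 1, 2, 3 and 4. Within groups, the members of set a correlated at a median r of 0.88, and 0 of them share 20 or more bases with another member.

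Probes that share sequence measured like changes. Among 1051 pairs of tested rclstr probes sharing 20 or more bases on the same strand, the log2 changes correlated across pairs at r = 0.87 for model versus control, 0.72 for BHD versus model and 0.82 for BHD versus control. For 764 such CIRCpedia pairs the values were 0.53, 0.31 and 0.41, and for 444 pairs of a CIRCpedia and an rclstr probe they were 0.57, 0.31 and 0.49. Draws of 1000 random pairs gave r between -0.10 and 0.09. The 365 rclstr pairs whose sequences match on opposite strands gave 0.47, 0.41 and 0.49.

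Among tested probes, 23 rclstr probes were on in some arrays and off in others, with a gap of 2.01 to 6.51 log2 units wider than 1.5 times the range on either side. They showed 18 different patterns over the arrays, and at most 3 probes shared a pattern, which are members of set a. Arrays simulated 100 times from normal scatter with each probe's own spread gave 0.21 such probes on average and at most 3. Against the 23 seen, this argues against normal scatter as the source of most of them. The average but not the highest number met the bound set for excluding it, a number under 10% of 23. Scatter of another shape was not simulated and stays open. A slide or group difference that parts the arrays completely is argued against, since 0 of the 23 part the slides or part a pair of groups completely. A partial slide or group difference was not tested and stays open. A candidate explanation is a difference between individual animals, such as a sequence variant under the probe, which was not tested.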
